A study of Mus musculus with 2 samples.

How the data were processed

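ATAC-seq libraries, made by Nextera tagmentation per the labels, came from the neural tube of healthy mouse embryos at 11.5 days, with 1 group and 2 biological replicates of pooled embryos. Coordinates are mm10, the build the labels name. The authors deposited lists of peaks for each library and for the pooled libraries. Aligner, peak caller, their versions and any shift of reads for the Tn5 insertion site are not given in the sources used here. The main list of each replicate was that of peaks found in both pseudoreplicates of the library, per the file list deposited with it. A stricter list passed a threshold on the irreproducible discovery rate (IDR), and a ranked list held the peaks before that threshold. The filtered lists had 1 more parent file than the ranked lists, and it was not used here. Fold enrichment, a ratio of the signal at each summit over local background, is the authors' value per summit as deposited. The −log10 p and −log10 q per summit are also the authors' deposited values. The smallest −log10 p was 2, a p of 0.01, and these values grow with read depth. Read depth is unknown, so no counting interval was computed for fold enrichment, and 2 replicates limit the precision of every SD. Lists of the pooled libraries were used only for overlap and for 1 alternative. In that alternative the pooled ranked list gives 2 columns of −log10 p from the libraries, which are not labelled by library. A further 3 pooled lists were not used.

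Summits with the same start and end were joined into 1 region with the highest fold among them, and its summit was used for position. A region was shared when it overlapped a region of the other replicate by at least 50% of the shorter of the pair. Shares were set beside 100 random circular shifts of the regions along each chromosome, with 95% Wilson intervals over regions. Genes and transcript starts were those of GENCODE M21, and sequence was the GRCm38 reference. A summit was a promoter summit within 1 kb of any protein-coding transcript start, and otherwise exonic, intronic or intergenic by the genes of every type. A gene's promoter was accessible when a region overlapped 1 kb either side of any of its starts. A region near the starts of neighbouring genes thus counted for each of them. Distal regions were given to the protein-coding gene with the nearest start.

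The design, the 20 gene lists, the 33 consensus motifs and the alternatives were fixed before the data were examined, except where noted. There were 7 neural lists, 11 lists of other cell types or regions and 2 control lists, and 1 neural crest symbol had no match in the annotation. Promoters of each list were tested against all other protein-coding genes with a two-sided Fisher's exact test per replicate. Benjamini-Hochberg adjustment ran over 40 tests, and a list was called when it passed 0.05 in the same direction in both replicates. These tests run over genes within a library and do not measure the spread between embryos. Distal regions of a list were described by the percentile of its median among 10000 random lists of the same size, matched on 10 strata of territory length. Percentiles count ties at mid-rank. A list was called higher above 97.5 and lower below 2.5 in both replicates, a limit set after the design. Ties ruled out the lower call for all 20 lists by the median. Territory was computed as the stretch of chromosome nearest to a gene's starts, whereas the design had named the distance between the midpoints of neighbouring genes. Hox groups 1 to 9 and 10 to 13 were compared with Fisher's exact test per replicate. The −log10 p of shared regions was compared between replicates at equal fold by the ratio of medians, averaged on the log scale over 20 bins of fold, with a 95% interval from 1000 bootstrap draws over regions.

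Motif matches on either strand were counted within 100 bp of each distal summit and in windows of 200 bp centred 1 kb to either side. The ratio of shares has a 95% interval from 1000 bootstrap draws over regions. A motif was called when the interval excluded 1 in both replicates, without correction over motifs. An interval was left undefined where matches were too few, a rule set after the result for HNF1 was seen. Named genes follow a rule fixed in advance. It took the 3 members of each list with the strongest promoters, and up to 5 members without a promoter region for neural lists or with one in both replicates for other cell types. It also took all Hox genes, the 10 strongest shared distal regions, the 15 genes with the most distal regions, and the 5 strongest regions of each replicate without overlap in the other.

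Alternatives were the IDR lists, a −log10 q of at least 5, equal numbers of regions, each replicate alone, promoter windows of 500 bp and 2.5 kb, overlaps of 1 bp or of 50% of both regions, summits within 50 bp, unmatched random lists, regions within 100 kb of a start, windows of 100 bp, dinucleotide shuffling and the strongest distal regions. Matching on CpG content within 500 bp of starts and the mean in place of the median were added after seeing the data. On simulated data with known answers, a planted sharing of 60.1% over 44018 regions was recovered as 60.4%. Of 100 planted promoter lists 71 were recovered, and of 100 background lists 1 was called. Of 100 lists with a planted 3-fold excess of distal regions 100 were called, and of 100 lists without one 2 were. Both simulations of lists used a single library, whereas the calls here needed both replicates. The distal lists were drawn only from genes of long territory, with counts that followed territory length. Their recovery thus does not show the power for lists with a median of 0. A planted motif ratio of 3.03 over 5000 regions was recovered as 3.04. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6, pysam 0.24.0, matplotlib 3.10.9, samtools 1.23.1 and BLAST 2.17.0 were used.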

Results

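Accessible chromatin was profiled in the neural tube, the embryonic structure that forms the brain and spinal cord, of mouse embryos at 11.5 days of gestation. The assay was ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into accessible DNA. There was 1 group with 2 biological replicates of strain B6NCrl, each pooled from male and female embryos. Replicate 1 came from 46 embryos and replicate 2 from 88. No other condition was measured, so the replicates were compared with each other, and classes of genes and genomic positions were compared within each replicate. Which levels of the body axis the dissected tissue covered is not given in the sources used here. Replicate 1 held 82956 summits in 44018 accessible regions, which covered 27.7 Mb with a median width of 511 bp and a median fold enrichment of 4.25. Replicate 2 held 68359 summits in 33717 regions, which covered 22.5 Mb with a median width of 561 bp and a median fold enrichment of 4.62. Read depth is unknown because only peak lists were used, and the fold enrichment of a region is the authors' value.

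The replicates were compared to learn which accessible regions recurred. Regions at promoters of protein-coding genes recurred most often. Of the promoter regions, 88.6% in replicate 1 and 92.5% in replicate 2 had a counterpart in the other replicate, against 42.1% and 71.9% of intergenic regions. By gene, 12943 of 21938 protein-coding genes had a promoter region in both replicates, 8075 in neither and 920 in a single replicate, so that 95.8% of genes had the same state. Over all regions, 60.05% of replicate 1 were shared (95% Wilson interval 59.6 to 60.5) and 80.9% of replicate 2 (80.5 to 81.3). Random circular shifts along the chromosomes gave means of 1.15% and 1.501%. Sharing followed signal. In replicate 1, 19.9% of the lowest fold quartile and 99.2% of the highest were shared, and in replicate 2 these shares were 53.5% and 99.9%. Across 25922 paired regions, which are not independent replicates, fold enrichment correlated with Spearman's rho of 0.837 and Pearson's r of 0.846 on the log2 scale. It was 1.125 times higher in replicate 1, and the log2 ratio had an SD of 0.36, with 98.9% of pairs within 2-fold. The authors' conservative list of the pooled libraries held 19157 regions, of which 99.5% overlapped replicate 1 and 98.1% replicate 2. Their replicated list held 43918, of which 76.0% and 65.9% did.

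**Figure D1:**
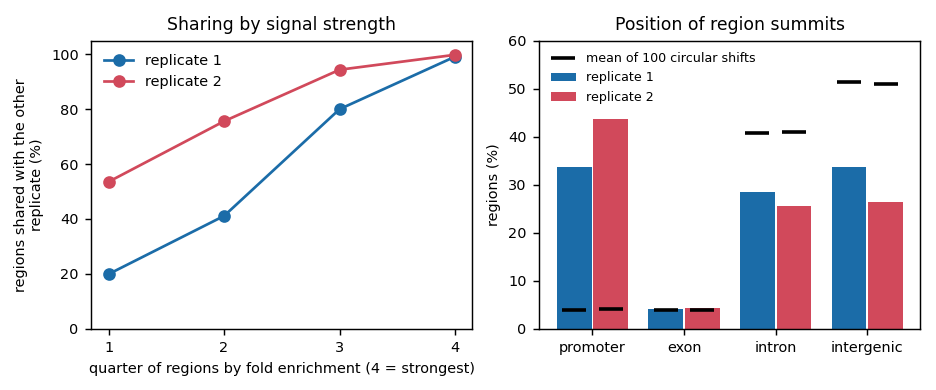
Left, percentage of regions shared with the other replicate (y axis) by quartile of fold enrichment (x axis, 4 strongest) for replicates 1 and 2. Right, percentage of region summits by position (bars) with the mean of 100 circular shifts (black lines); promoters hold 33.7% and 43.7% of summits against 3.90% and 3.98% after shifting.

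The strongest regions with no overlap in the other replicate were mostly intronic or intergenic, and none had a gene of the lists below as its nearest protein-coding start. In replicate 1 the strongest was in an intron at chromosome 16:18533121-18533386 (mm10), nearest to Gnb1l, at 19.7-fold. It was followed by the promoter of Tmem169 at chromosome 1:72283972-72284545 (12.9-fold), an intron nearest to Gm21738 (9.68-fold), an intergenic region nearest to Tsc22d2 (9.53-fold) and an intron nearest to Vbp1 (9.22-fold). In replicate 2 the strongest was intergenic at chromosome Y:259030-259510, nearest to Zfy1 (9.77-fold). It was followed by an intron nearest to Ptprt (7.44-fold) and intergenic regions nearest to Igfbp3 (7.203-fold), Prmt6 (7.13-fold) and Cd200 (7.08-fold).

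Accessible regions were concentrated at promoters. A summit within 1 kb of a protein-coding transcript start was found for 33.7% of regions in replicate 1 and 43.7% in replicate 2 (38.7% ± 7.02, SD, n = 2). These shares were 8.64 and 10.98 times the means after shifting, 3.90% and 3.98%. Introns held 28.4% and 25.6% of summits against 40.8% and 41.01% after shifting, and intergenic sequence 33.8% and 26.4% against 51.4% and 51.05%. These 3 classes lay outside the range of the 100 shifts in both replicates, whereas exons, with 4.09% and 4.23% against 3.93% and 3.96%, lay inside it. The classes share a fixed total, so the excess at promoters lowers the shares of the others. Shares among summits outside promoters were not compared, so these values show neither a depletion of introns nor the lack of an exon excess. Promoter regions also had the highest median folds, 7.199 and 6.10, against 3.56 and 4.14 for intergenic regions. The mean promoter share was 67.8% with the authors' lists that pass a threshold on the irreproducible discovery rate (IDR).

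Genes of neural progenitors and of neurons in general had promoter regions more often than other genes. All 20 progenitor genes had a region within 1 kb of a start in both replicates, against 61.9% and 60.2% of the other protein-coding genes (adjusted p = 0.000364 in each, two-sided Fisher's exact test with Benjamini-Hochberg adjustment over 40 tests). The strongest were Hes6, a basic helix-loop-helix factor (fold enrichment 7.43 ± 0.892, SD, n = 2), Fabp7, a fatty acid binding protein of radial glia (7.39 ± 0.359), and Msi1, an RNA-binding protein of neural stem cells (6.95 ± 0.255). Of the 23 pan-neuronal genes, 22 had a promoter region in replicate 1 and 21 in replicate 2 (adjusted p = 0.00108 and 0.00507, Fisher's exact test). Syt1, which encodes a calcium sensor of synaptic vesicles (chromosome 10:108497650-109010982), had the strongest promoter region of these genes, at 17.02-fold and 11.7-fold. It was followed by Elavl4, an RNA-binding protein of neurons (9.96 ± 0.812), and Map2, a dendritic microtubule protein (9.33 ± 1.98). Nhlh2 had no promoter region in either replicate. The 20 housekeeping genes, a positive control, all had a promoter region in both replicates (adjusted p = 0.000364 in each, Fisher's exact test), led by Vcp (13.2 ± 1.16), Eef1a1 (11.3 ± 0.903) and Rplp0 (10.6 ± 4.16). With the IDR lists the pan-neuronal list passed only in replicate 1, with promoter regions at 19 and 14 of its 23 genes. Against random lists matched on promoter CpG content, an alternative chosen after seeing the data, the pan-neuronal list was higher (percentile 100 in both). The progenitor list (100% against 95% and 90%) and the housekeeping genes (100% against 95% in both) could not be tested for an excess in this way, since a list at 100% was tied with too many random lists to pass in both replicates.

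Lists of factors that set position and neuron subtype did not differ from other genes in both replicates. Of the 15 ventral patterning genes, 10 and 11 had a promoter region (adjusted p = 0.85 and 0.555, Fisher's exact test). The strongest were Nkx6-1, a homeobox factor of ventral progenitors (chromosome 5:101658139-101664996, 10.5 ± 4.34), Arx (9.296 ± 2.28) and Irx5 (7.87 ± 0.954). Shh, the floor plate signal, Dbx1 and Nkx2-9 had none within 1 kb of a start in either replicate. Of the 17 dorsal patterning genes, 13 and 11 had a promoter region (adjusted p = 0.454 and 0.85, Fisher's exact test), led by Msx2 (6.93 ± 2.198), Atoh1, a proneural factor (5.96 ± 0.474), and Zic5 (5.13 ± 0.101). The secreted signals Wnt1, Wnt3a, Gdf7 and Rspo1 had none. Of the 30 neuron subtype factors, 25 had one in replicate 1 and 20 in replicate 2 (adjusted p = 0.0251 and 0.691, Fisher's exact test). The LIM homeobox factor Isl2 (9.602 ± 1.86), Sim1 (9.404 ± 3.21) and the motor neuron factor Isl1 (8.68 ± 2.43) led that list, while Barhl1, Evx1, Evx2, Sox14 and Vsx2 had none. Of the 20 forebrain and midbrain factors, 13 and 11 had one (adjusted p = 1.0 and 0.731, Fisher's exact test). Among them were Dlx1 (7.75 ± 1.31), Dlx6 (6.39 ± 1.64), the telencephalic factor Foxg1 (6.298 ± 1.105), Otx1 (6.105 ± 1.465) and En2 (5.7 ± 2.36). With replicate 1 alone 5 lists were higher than other genes, the subtype factors and Hox groups 1 to 9 in addition to the 3 that passed in both. With a window of 2.5 kb, 14 and 13 of the 15 ventral genes had a promoter region (adjusted p = 0.0321 and 0.0983, Fisher's exact test). Absences in the ventral list thus depended on the window. Dorsal genes stayed at 13 and 11, while subtype factors had 26 and 21 and forebrain and midbrain factors 15 and 14.

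Genes of mature or non-neural cell types mostly lacked promoter regions. The share was lower than among other genes in both replicates for 7 lists (Fisher's exact test). These were mature glia (3 and 1 of 12 genes, adjusted p = 0.0249 and 0.00108, exact test), erythroid genes (2 and 3 of 14, 0.00108 and 0.00952), and microglia and other leukocytes (1 and 0 of 14, 0.000251 and 3.29e-05). Skeletal muscle genes (1 and 3 of 15, adjusted p = 0.000127 and 0.00513, exact test), heart genes (4 and 3 of 15, 0.0135 and 0.00513) and liver genes (3 and 3 of 16, 0.00151 and 0.00314) were lower too. Of the olfactory and vomeronasal receptors, a negative control, 35 and 5 of 1420 had a promoter region, against 66.1% and 64.4% of other genes, with p-values below the range of the number format. Members with a promoter region in both replicates were Aldh1l1 among the glial genes, the erythroid factor Klf1, the muscle gene Mylpf, the heart genes Actn2 (11.9 ± 2.85), Myl3 and Hand2, and the liver genes Foxa3 (8.88 ± 1.902), Afp and Apob. The strongest receptor promoters were those of Vmn1r4 (10.2 ± 1.35), Olfr658 (7.46 ± 1.16) and Olfr94 (6.75 ± 0.419). Their promoter CpG content, observed over expected, was 0.895, 0.41 and 0.417 against a list mean of 0.155. Whether the regions of these and the other named members belong to neighbouring genes was not examined. With a window of 2.5 kb the mature glia (6 and 2 of 12) and liver lists (6 and 5 of 16) passed only in replicate 2. With CpG-matched lists none of these 6 cell-type lists was called (percentiles of 40.2 and 4.29 for mature glia, 41.7 and 78.3 erythroid, 19.9 and 5.2 leukocytes, 0.215 and 15.5 skeletal muscle, 6.62 and 2.58 heart, 29.6 and 36.02 liver), and the receptors were lower. The leukocyte list could not have been called lower in that setting, even with no promoter region.

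Genes of tissues next to the neural tube were not lower in both replicates. Promoter regions were found at 10 and 11 of 14 neural crest and sensory ganglion genes (adjusted p = 0.691 and 0.273, Fisher's exact test), among them Mpz, a myelin protein of Schwann cells (11.1 ± 1.63), Eya1 (7.47 ± 2.496), Pou4f1 (7.41 ± 2.71), Ednrb and Six1. They were found at 15 and 14 of 21 sclerotome and mesenchyme genes (adjusted p = 0.626 and 0.731, exact test), among them Pax9 (8.83 ± 0.721), Meox2 (6.34 ± 0.509), Pdgfra (6.32 ± 0.207), Foxd1 and Col1a1. Of the 14 endothelial genes, 7 had one in each replicate (adjusted p = 0.555 in both, exact test), among them Erg (6.997 ± 1.62), Kdr (5.85 ± 0.958), Egfl7, Flt4 and Esam. Of the 13 genes of surface ectoderm and epithelium, 4 and 3 had one (adjusted p = 0.0674 and 0.0167, exact test), including Perp, Grhl2 and Krt8. Whether the regions of the members named here, such as Mpz, belong to neighbouring genes was not examined either. With the IDR lists the endothelial list (2 and 1 of 14 genes) and the surface ectoderm list (1 and 0 of 13) were lower in both replicates, and the latter also with −log10 q of at least 5 (3 and 2) and with a window of 500 bp (3 and 1). Against CpG-matched lists the surface ectoderm, forebrain and midbrain and Hox 10 to 13 lists were lower in both replicates.

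**Figure D2:**
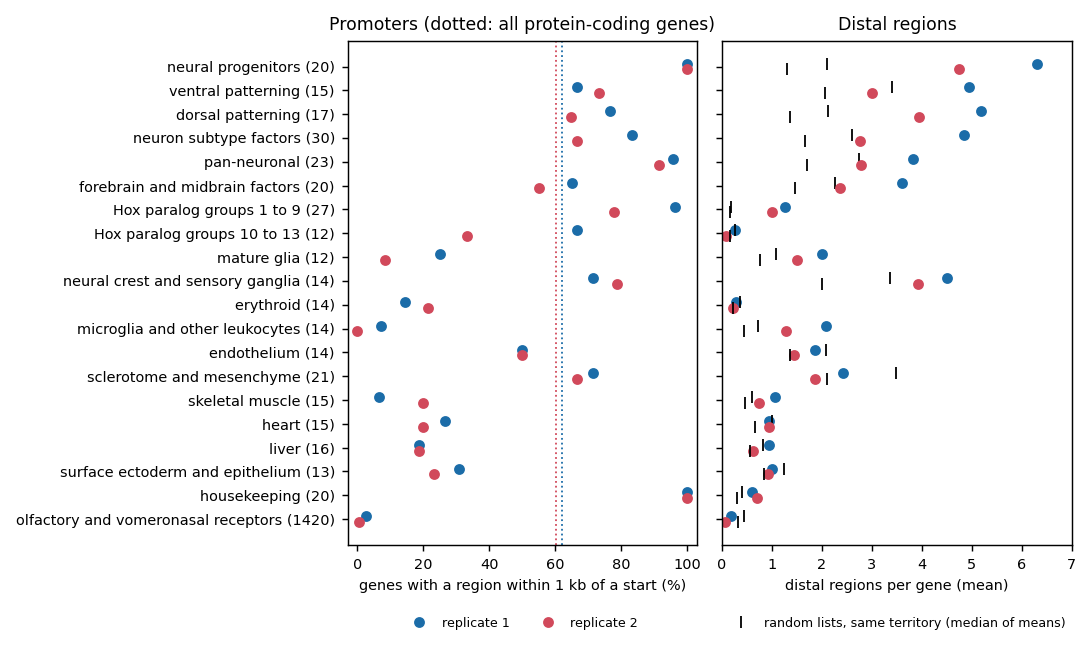
Left, percentage of the genes of each list (number of genes in brackets) with a region within 1 kb of a transcript start, per replicate, with dotted lines for all protein-coding genes (62.0% and 60.2%). Right, mean number of distal regions per gene, with black ticks for the median of the means of 10000 random lists of matched territory; neural progenitors have 6.3 and 4.75 against 2.1 and 1.3.

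Away from promoters, the genes of progenitors, dorsal patterning, neuron subtypes, neurons in general and the forebrain and midbrain had more accessible regions than genes with territories of similar length. Distal regions, with a summit over 1 kb from every protein-coding start, numbered 29168 in replicate 1 and 18992 in replicate 2, a mean of 1.33 and 0.866 per gene. Progenitor genes had medians of 4.5 and 3 distal regions, against 0.5 and 0 in random lists (percentile 100 in both replicates). Dorsal patterning genes had medians of 5 and 3 against 1 and 0 (percentile 100 in both), and subtype factors 4 and 3 against 1 and 1 (100 in both). Pan-neuronal genes had medians of 3 and 2 against 1 and 0 (percentiles 99.5 and 99.2), and forebrain and midbrain factors 2.5 and 2 against 1 and 0 (99.5 and 99.6). Genes without a promoter region could still have distal ones, such as Nhlh2 (5 and 6), Sox14 (5 and 5), Barhl1 (4 and 2) and Shh (4 and 2). Ventral patterning genes (percentiles 98.1 and 90.35), Hox groups 1 to 9 (100 and 50), mature glia (96.2 and 94.1) and neural crest genes (95.3 and 98.8) passed in at most 1 replicate. The other 11 lists lay between percentiles 36.4 and 96.7: Hox groups 10 to 13, erythroid, leukocyte, endothelial, sclerotome and mesenchyme, skeletal muscle, heart, liver, surface ectoderm, housekeeping and receptor genes. With the IDR lists, and with −log10 q of at least 5, the progenitor and dorsal patterning lists were the only ones higher. With regions within 100 kb of a start, forebrain and midbrain factors were not called and both Hox lists and neural crest genes were higher, and with a promoter window of 2.5 kb the pan-neuronal list passed only in replicate 2 (percentiles 95.1 and 99.3). Within 100 kb a region counted for every gene in reach, so Hox genes of the same cluster counted many of the same regions and were not independent. By the median none of the 20 lists could be called lower, because a median of 0 was tied with too many random lists. By the mean in place of the median, an alternative chosen after seeing the data, the pan-neuronal and the forebrain and midbrain lists were not called, Hox groups 1 to 9 were higher and the receptors lower.

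Ranked by the lower of their numbers in both replicates, the gene with the most distal regions was Celf4, an RNA-binding protein of neurons (chromosome 18:25477632-25754157), with 50 in replicate 1 and 34 in replicate 2. It was followed by Tenm4 (34 and 30), Zfp608 (40 and 28), the synaptic adhesion gene Nrxn3 (27 and 27), Gse1 (42 and 26), the axon guidance receptor Robo1 (38 and 26), Adgrl2 (38 and 25) and the progenitor factor Sox9 (31 and 25). Mef2c (38 and 24), Rapgef5 (31 and 23), the nuclear receptor Nr2f1 (35 and 22), Smim15 (22 and 22), the Hox cofactor Meis1 (29 and 21), Efnb2 (25 and 21) and Nav2 (23 and 21) completed the 15 highest. All 15 had territories in the longest of 10 strata, and a ranking by number favours such genes. Per 100 kb of territory Celf4 had 1.88 and 1.28 regions and Gse1 11.2 and 6.92, and the 14 genes other than Gse1 had 1.39 to 4.02 in replicate 1 and 1.07 to 3.87 in replicate 2. The stratum medians were 0.981 and 0.497.

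The Hox genes, whose paralog groups are used in sequence along the body axis, were compared between groups 1 to 9 and the more posterior groups 10 to 13. Promoter regions were more frequent in groups 1 to 9. They were found at 26 of 27 genes of these groups in replicate 1 and 21 of 27 in replicate 2, against 8 of 12 and 4 of 12 genes of groups 10 to 13 (adjusted p = 0.0246 in both, two-sided Fisher's exact test over 2 tests). The differences were 29.6 and 44.4 points. Against all other protein-coding genes, groups 1 to 9 were higher in replicate 1 alone (adjusted p = 0.000364 and 0.117, exact test), and groups 10 to 13 did not pass (1.0 and 0.117). All genes of groups 1, 4, 5, 7, 9 and 10 had a promoter region in both replicates. Group 11 had 1 of 3 in replicate 1 and 0 in replicate 2, and group 12 had 0 of 2 in both. Group 13 had 4 of 4 and 1 of 4, group 2 had 2 of 2 and 1 of 2, group 3 had 3 of 3 and 2 of 3, group 6 had 3 of 3 and 1 of 3, and group 8 had 2 of 3 and 1 of 3. Hoxd1 (6.57 ± 2.86, SD, n = 2), Hoxb9 (6.54 ± 0.17) and Hoxb1 (6.004 ± 0.204) had the strongest promoters of groups 1 to 9. Hoxd10 (7.39 ± 2.34), Hoxc13 (6.96 ± 3.03) and Hoxc10 (5.27 ± 1.44) had those of groups 10 to 13, and Hoxb8, Hoxa11, Hoxc11, Hoxc12 and Hoxd12 had none. The Hoxa cluster (chromosome 6:52155590-52260880) held 26 and 20 regions, Hoxb (chromosome 11:96194316-96368256) 19 and 12, Hoxc (chromosome 15:102921103-103036852) 16 and 7, and Hoxd (chromosome 2:74668310-74765142) 21 and 19. The difference no longer passed in both replicates with the IDR lists (mean of 31.5 points), with −log10 q of at least 5 (33.8) or with equal numbers of regions (27.8). With equal numbers the promoter regions of replicate 1 were at 21 of 27 against 8 of 12 genes, and those of replicate 2 at 21 of 27 against 4 of 12. Annotated starts of neighbours lie close together here, so that Hoxc5 and Hoxc10, and Hoxd3 and Hoxd4, took their strongest value in replicate 1 from the same region. Fisher's exact test takes such genes as independent, so its p-values for the Hox groups may be too small.

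**Figure D3:**
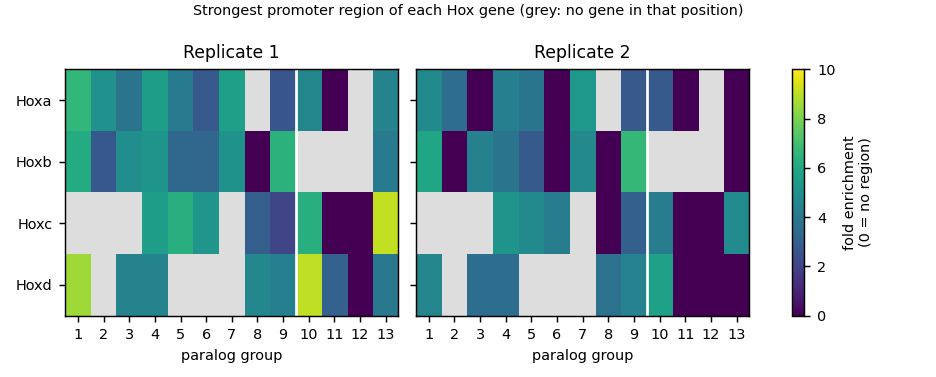
Fold enrichment (colour, 0 where no region was found) of the strongest promoter region of each Hox gene, by cluster and paralog group, per replicate; grey squares have no gene and the white line parts groups 1 to 9 from 10 to 13. Groups 11 and 12 have a promoter region at 1 gene in replicate 1 and at 0 in replicate 2.

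Consensus motifs at distal summits were compared with flanks 1 kb away to see which factor families mark accessible sites. Of 33 motifs, 17 were more frequent at summits in both replicates (95% bootstrap interval of the ratio above 1), 5 were less frequent and 11 were not called. The insulator motif CTCF was found at 5.49% and 4.44% of distal summits, 34.8 times (28.7 to 43.6) and 22.5 times (18.2 to 28.98) the flank share. RFX followed at 12.4 and 11.8 times. Among families of neural progenitors and patterning, the E-box CAGCTG of Ascl1 type was 2.26 times (2.18 to 2.34) and 2.32 times (2.23 to 2.42) as frequent as in flanks, at 19.1% and 21.4% of summits. The SOX motif was at ratios of 1.74 (1.66 to 1.81) and 1.81 (1.72 to 1.91), ZIC at 2.2 and 2.207, the POU octamer at 2.15 and 1.91, the composite HOX and PBX motif at 2.19 and 2.24, and MEIS at 1.55 and 1.504. GLI, the family that responds to Shh signalling, was at 2.13 and 1.64, RBPJ, the effector of Notch signalling, at 1.33 and 1.395, and the E-box CAGATG at 1.3 and 1.34. NRF1 (6 and 4.67), NFI (5.71 and 3.6), KLF and SP (4 and 3.797), ETS (1.93 and 2.3), NFY (1.81 and 1.957) and TEAD (1.14 and 1.15) were also more frequent. Matches were rare for NRF1, at 0.0926% and 0.111% of summits (intervals 3 to 16 and 2.18 to 12). They were rare too for NFI, at 0.0686% and 0.0474% (2.73 to 21 and 1.2 to 16), and for ETS, at 0.0926% and 0.121%.

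Of the motifs with an interval, GATA was furthest below its flanks, at 0.58 (0.524 to 0.64) and 0.607 (0.527 to 0.694). SRF (0.762 and 0.737), FOX (0.823 and 0.663), ONECUT (0.836 and 0.682) and the E-box CATATG of Neurog and Atoh type (0.902 and 0.728) were lower too. The homeodomain core TAATTA went in opposite directions, 1.21 (1.15 to 1.27) in replicate 1 and 0.789 (0.733 to 0.848) in replicate 2. The E-box CAGGTG (1.01 and 0.928), the nuclear receptor motif (1.01 and 1.04), YY1 (3 and 2.8), AP1 (1.05 and 1.09), HNF4 (0.808 and 0.903), MEF2 (0.904 and 0.832), PU1 (0.821 and 0.88) and TCF and LEF (0.911 and 0.891) were not called. HNF1 and REST had too few matches for an interval. With the IDR lists the mean ratio of RFX was 33.7, CTCF 17.4, NRF1 10.2, KLF and SP 6.18, ETS 4.83, NFY 3.995, GATA 0.369 and ONECUT 0.443, while NFI, TEAD, SRF, GLI and RBPJ were not called and the homeodomain core (0.785) and CAGGTG (0.722) were lower. CAGGTG was also lower with −log10 q of at least 5 (0.878) and in the strongest quartile of distal regions (0.797). With windows of 100 bp NRF1, ETS, TEAD and CATATG were not called and AP1 (1.14) was higher. Against the same windows with shuffled dinucleotides, FOX (1.68), the homeodomain core (2.25), MEF2 (1.77), PU1 (1.26) and YY1 (9.5) were higher and CAGGTG (0.707) and the nuclear receptor motif (0.945) lower. In that setting CATATG (1.09) and ONECUT (1.01) were above 1 and not called, as were NFI and GLI, and the HOX and PBX motif was at 4.88, the POU octamer at 3.38 and CAGCTG at 1.47.

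**Figure D4:**
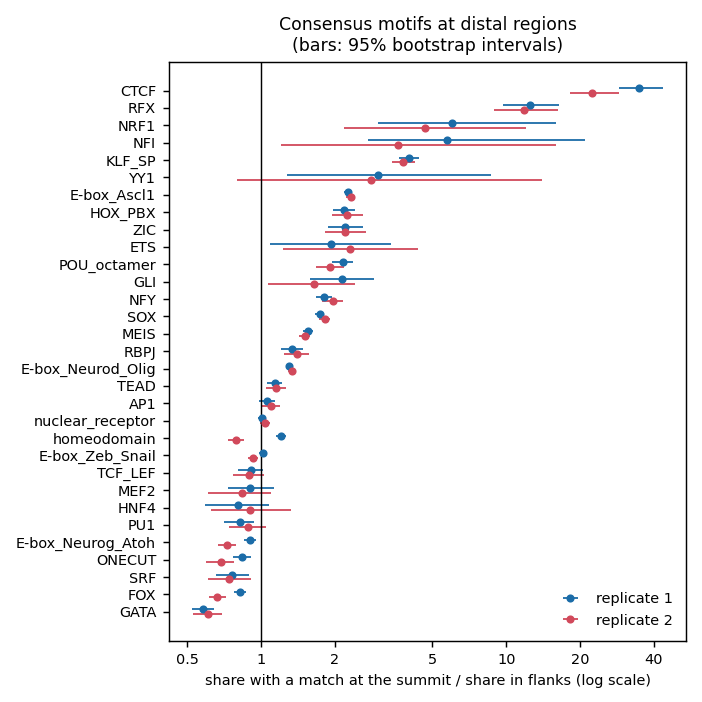
Ratio of the share of distal regions with a consensus match within 100 bp of the summit to the share in flanks (x axis, log scale), with 95% bootstrap intervals, per motif and replicate; HNF1 and REST are not drawn. CTCF is furthest above 1 (34.8 and 22.5) and GATA furthest below (0.58 and 0.607).

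The strongest distal regions shared by the replicates did not have a gene of the fixed lists as their nearest protein-coding start. The strongest was intergenic at chromosome X:143482934-143483180 (mm10), 35531 bp from the start of Pak3, with a fold enrichment of 53.6 ± 0.589 (SD, n = 2). The next were at chromosome 2:69355470-69355735 (intergenic, nearest to Abcb11, 47.5 ± 7.01), chromosome 10:96077546-96077953 (intron, Gm5426, 39.9 ± 1.77), chromosome 2:3964426-3964689 (intergenic, Frmd4a, 35.7 ± 4.42) and chromosome 5:60042765-60043138 (intergenic, G6pd2, 34.5 ± 2.77). They were followed by chromosome 12:97061368-97061856 (intergenic, Galc, 28.3 ± 0.69), chromosome X:76598488-76599189 (intron, Cldn34d, 23.6 ± 0.481) and chromosome 4:80002696-80003057 (exon, Tyrp1, 23.4 ± 3.03). The last were chromosome 9:123461727-123462252 (exon, Lars2, 23.3 ± 3.76) and chromosome 6:9889880-9890225 (intergenic, Nxph1, 23.2 ± 3.05). The nearest starts of G6pd2, Galc, Tyrp1 and Nxph1 were between 831186 and 1765841 bp away. Of these 10 regions, 6 matched the mitochondrial genome over at least 50 bp at 80% identity or more, against 6 of 12963 other shared distal regions: those nearest to Abcb11, Gm5426, G6pd2, Galc, Tyrp1 and Nxph1.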

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

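No test in this part was chosen after its result was seen. The ranked lists, which no comparison above uses, held regions that the filtered lists lack. On unplaced scaffolds there were 110 in replicate 1 and 59 in replicate 2. On the 21 chromosomes there were 1971 and 1636 without a counterpart in the filtered list. Most were weak, with median folds of 2.46 and 2.69, but 40 and 26 of them had a −log10 p above 50, and 87 were left out in both replicates. The strongest lay at chromosome 1:24611586-24616163 (mm10), nearest to Col19a1, with −log10 p of 5330 and 3586, above the highest kept values of 4950 and 2534. It matched the mitochondrial genome over 4578 bp at 99.96% identity. The next, at chromosome 6:103648978-103649357, had folds of 42.3 in both replicates.

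A single pattern concerns the strongest regions, both the 10 strongest distal ones that were kept and the 10 strongest that were left out. Among the latter, mitochondrial copies as the general cause are argued against, since 1 of 10 had a mitochondrial match. Among the kept ones, copies of mitochondrial DNA in the nuclear genome stay open as a candidate explanation, since 6 of 10 had a match, against 0.0463% of other shared distal regions. Sequence present in several copies was not decided, since 4 of 10 had a copy elsewhere, fewer than the majority it needed and more than the bound of 1 for random draws from only 200 sampled regions, and all 4 are among the 6 with a mitochondrial match, in a search that included the mitochondrial genome. No biological explanation was tested, because the design holds a single group.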

How the results depend on the processing

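Alternatives chosen after seeing the data were CpG matching and the mean in place of the median. With the IDR lists the regions numbered 17513 and 12102. The shared percentage of replicates 1 and 2 was 65.2 and 94.8 with the IDR lists, 66.5 and 90.2 with −log10 q of at least 5, 72.6 and 75.6 with equal numbers of regions, 60.8 and 82.2 with an overlap of 1 bp, and 52.4 and 68.4 with 50% of both regions. Spearman's rho was 0.812 (IDR lists), 0.83 (−log10 q of at least 5), 0.829 (equal numbers), 0.861 (summits within 50 bp) and 0.669 (−log10 p in the pooled ranked list). The mean promoter share was 67.8% with the IDR lists and 48.1% with −log10 q of at least 5, and 33.7% to 43.7% with each replicate alone. The 3 lists with more promoter regions became 3 to 5 with each replicate alone and 1 with CpG matching, where the 2 that lost the call, at 100%, could not pass because of ties. The 7 with fewer numbered 4 with CpG matching, the receptors from among the 7 and 3 lists not called before (forebrain and midbrain, Hox 10 to 13, surface ectoderm), while ties kept the leukocytes from passing. The 5 lists with more distal regions became 2 with the IDR lists, 2 with −log10 q of at least 5 and 8 with random lists not matched. With regions within 100 kb of a start 7 were higher: forebrain and midbrain factors lost the call (percentiles 96.4 and 79.1), while both Hox lists (100 in both replicates) and neural crest genes gained it. Hox genes of the same cluster counted many of the same regions there, whereas random lists hold scattered genes, so the Hox percentiles are not those of independent genes. Lists with fewer, which numbered 0 in the main setting because ties ruled that call out for all 20, became 1 with regions within 100 kb of a start and 1 with the mean. The Hox difference of 37.04 points lost its call at 31.5 (IDR lists), 33.8 (−log10 q of at least 5) and 27.8 (equal numbers). Among results called in the main or the alternative setting, the erythroid promoters turned direction with CpG matching (3.57 points above matched lists). That rests on replicate 2 (21.4% against 14.3%), since replicate 1 was level at 14.3%. With dinucleotide shuffling the ratios minus 1 turned for CATATG (0.0858), FOX (0.684), ONECUT (0.00712), MEF2 (0.766), PU1 (0.258), the nuclear receptor motif (-0.0547) and the homeodomain core (1.25), which with each replicate alone ranged from -0.211 to 0.208. Results called in neither setting could turn too. Promoters of ventral and dorsal patterning, subtype and neural crest genes went from above other genes to below CpG-matched lists, and AP1 fell to a ratio of 0.969 with shuffling. No direction can be read for forebrain and midbrain distal regions with the IDR lists (percentile minus 50 of -0.388), since the list median of 0 is tied with random lists, nor for the main value of Hox 10 to 13 (50 with 100 kb), tied likewise. The cause was not tested for any of these changes, except for those ties and that fewer regions entered with the IDR lists, −log10 q of at least 5 and equal numbers. Of 20 promoter list results, 17 kept their call with the IDR lists, 19 with −log10 q of at least 5, 20 with equal numbers, 19 with 500 bp and 18 with 2.5 kb. Of 20 distal list results, 17, 17, 19, 19 and 19 did in the same settings, 17 with random lists not matched, 15 with 100 kb and 16 with the mean, and 9 of 20 promoter results did with CpG matching. Of 33 motifs, 33 kept their call with equal numbers, 29 with −log10 q of at least 5 and 22 with shuffling. With the IDR lists 24 of 31 motifs did and in the strongest distal regions 25 of 31, where HNF1 and REST gave no value, and 27 of 32 with windows of 100 bp. Unknown read depth limits what the absence of a region can show.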

Other observations

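The tests of weaker detection, a GC slope, neurons against progenitors and weak promoter signal, and the grouping of 6 lists from their CpG-matched values, were chosen after the result was seen. Distal regions of low GC content differed between the replicates. Under 40% GC at the summit there were 4198 distal regions in replicate 1 (14.4%), of which 8.72% overlapped replicate 2, and 625 in replicate 2 (3.29%), of which 58.2% overlapped replicate 1. The homeodomain core TAATTA, the target of many patterning factors, also differed between sets of regions. At regions shared by both it was at 0.871 and 0.804 of its flank share, at regions of replicate 1 alone at 1.45 (1.37 to 1.53), and at regions of replicate 2 alone at 0.749 (0.644 to 0.87). Mean GC at these summits differed as well, 53.3% and 53.2% at shared regions, 46.03% in replicate 1 alone and 51.1% in replicate 2 alone. Against shuffled dinucleotides, which keep base composition, TAATTA was higher at the distal regions of both replicates (1.92 and 2.59). The opposite directions thus depend on the background, and the sets were not compared at equal GC.

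Replicate 1 listed more regions than replicate 2, 44018 against 33717, although it came from fewer embryos. A broad excess of other cell types in replicate 1 was argued against only narrowly. Distal regions at their genes, without the forebrain and midbrain list, lacked an overlap about as often as those at neural genes (119 of 255 and 252 of 558, odds ratio 1.06, 0.78 to 1.45, Fisher's exact p = 0.705). That test pools the lists, is not matched on fold, and takes regions of the same gene as independent, so its interval may be too narrow. The upper bound of 1.45 lay just under the limit set in advance, so a slightly wider interval would leave a broad excess undecided. The test cannot exclude more cells of a single type either. A GC slope that favours replicate 1 at shared regions of low GC is argued against, since that needed a negative Spearman's rho. Rho of GC share and the ratio of replicate 1 to replicate 2 was 0.109 at distal shared regions and 0.187 at all shared regions. This positive slope runs opposite to the lower GC content of the distal regions of replicate 1 alone. A weaker detection in replicate 2 stays open, since at shared regions of equal fold the −log10 p of replicate 2 was 0.771 of that of replicate 1 (0.768 to 0.775), and so does a difference in GC content between the libraries, since distal regions of replicate 2 alone had 5.06 points more GC than those of replicate 1 alone (4.83 to 5.3), and more in each tertile of fold common to both (51.3 against 44.03, 50.95 against 46.02 and 51.1 against 48.3%), so that fold alone does not account for it. Regions at neuron genes lacked an overlap more often than those at progenitor genes (122 of 233 and 46 of 126, odds ratio 2.06 pooled over fold quartiles, 1.2 to 3.56), but the 52.4% at neuron genes was no excess over the 53.7% of all distal regions of replicate 1, so that more neurons relative to progenitors stay open only through the lower share of 36.5% at progenitor genes. This interval also takes regions of the same gene as independent, and Sox2 held 26 of the 126 progenitor regions. How much weaker detection, GC content and neurons each contribute was not estimated, and the design, with a single group, gives no biological difference between groups to test.

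Promoters of 121 genes that set position or neuron subtype held a region less often than those of genes with the same CpG content, 78.5% and 64.5% against 89.3% and 87.6%. These genes come from 6 lists grouped because of their CpG-matched values, of which only 2, forebrain and midbrain factors and Hox groups 10 to 13, were lower in both replicates; ventral patterning (percentiles 1.205 and 9.725), dorsal patterning (3.55 and 0.365) and subtype factors (10.7 and 0.04) passed in 1 replicate each, and Hox groups 1 to 9 in neither (95 and 12.6). Starts that lie outside the 1 kb window are argued against as the whole cause. With 2.5 kb the shares were 84.3% and 71.1% against 90.1% and 88.4% in matched lists, at or under percentile 1.24. The gap was narrower than with 1 kb in both replicates, so such starts stay open as a part of the cause. Grouping the genes by values of these same data also favours a low percentile with 2.5 kb. Weaker promoter signal stays open as a candidate explanation, since the accessible promoters had median folds of 4.61 and 4.41 against 8.41 and 7.003 in matched genes (percentile 0.0 in both replicates). Closeness to the detection limit is not shown by this. Those medians were near the medians of all regions, 4.25 and 4.62, and promoters without a region have no fold to compare. No biological explanation was tested.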
